A study of Homo sapiens with 6 samples.

How the data were processed

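RNA came from VK2/E6E7 cells treated for 6 h with PBS or with Lactobacillus salivarius HHuMin-U (HMU) at 1e8 CFU/mL, 3 biological replicates each per the series' design text, and was sequenced from TruSeq stranded mRNA libraries per the labels. 1 table of 46427 genes, with NCBI gene IDs and symbols, gave 3 columns of values per library. The deposited read counts, named so in the column headers, are whole numbers per gene and were taken as not normalised. The deposited FPKM values are scaled by transcript length and library, and the deposited TPM values are scaled by transcript length and to a fixed sum, per the file headers; they summed to 1000000 in each library. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the build GRCh38; which tool made the read counts, the annotation release, the treatment of reads with several matches and the use of strand are not given in the sources used here. The table heads its treated columns HMO-1 to HMO-3 where the sample labels write HMU; as the table's only columns besides the controls, with the same replicate numbers, they were taken as the HMU samples.

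Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 2 groups, which left 17990, and libraries were scaled by TMM, with factors from 1.10 to 1.11 for PBS and from 0.893 to 0.920 for HMU. The quasi-likelihood fit (glmQLFit with default settings, glmQLFTest) used the group as the only term, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-normalised counts per 1000000 (CPM), as mean ± SD of 3 libraries. The biological coefficient of variation was 11.9%. Where a gene had 0 counts in the PBS libraries, its fold was set against a floor of 3 counts per library; with 1 to 3 PBS counts the ratio has a 95% exact binomial interval. Floors and intervals cover counting error only. Depth was even, at 64292566 to 65957584 counts per library, so that 3 counts equal 0.0455 to 0.0467 CPM before TMM; the floors used the TMM-scaled PBS library sizes.

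Before the data were examined, 33 gene lists were fixed, 25 on pathways that fit vaginal epithelium and a bacterium and 8 background lists. Each was tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation and with fry; p-values were adjusted over all lists with at least 5 measured members. List counts come from the edgeR calls over all genes and, as stated, adjusted over the list alone. Named genes follow a rule fixed at the same time. It takes the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, passing over LOC genes, pseudogenes and small RNAs. It also takes the 2 called members with the largest change and at least 1 CPM in each study list with 3 or more calls, and the most abundant member of each background list. Other genes named, such as FAM83A, were chosen after their values were seen. Coordinates are those of NCBI's RefSeq annotation of GRCh38, matched by gene ID for 44698 of the 46427 genes (96.3%).

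The tests were tried on simulated counts with 50 genes changed at each of 4 fold sizes: edgeR made 3 calls among 17790 unchanged genes, and DESeq2 made 40. At 2-fold edgeR recovered 76% and DESeq2 82%. At 1.5-fold they recovered 22% and 60%; with so few changed genes the adjusted p is stricter there than in the real data, so these shares are no measure of power in this comparison. A raised list was called by camera, and 0 of 50 random lists were. Genes were simulated independently, so this does not test lists whose members move together. Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood fit, RLE scaling, library sizes only, no filter on low counts or a filter of 1 CPM in 3 libraries, stricter thresholds, a prior count of 0.5 for lists, a replicate block, leaving out each library, and limma-trend on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1). Alternatives added after seeing the data were the robust quasi-likelihood fit, a correction for transcript length and GC content, leaving out readthrough and antisense genes, library sizes only for the list tests and counts, and list medians without each library. The robust fit was run first and replaced by the default fit, which the fixed design implied, after its counts had been seen. The length and GC correction removed a loess trend (span 0.5) of each library on the length and GC content of the longest GENCODE 29 transcript, known for 88.0% of tested genes. Whether reads align to the bacterium was not analysed here.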

Results

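The series measured gene expression by stranded mRNA sequencing in VK2/E6E7 cells, an established line of human vaginal epithelial cells immortalised with papillomavirus E6 and E7 genes. Cells received PBS or Lactobacillus salivarius HHuMin-U (HMU), a lactic acid bacterium, at 1e8 CFU/mL for 6 h, with 3 biological replicates in each group. The deposited table lists 46427 genes. Total counts were 64292566, 64694835 and 65593367 in PBS replicates 1 to 3, and 65250961, 64370749 and 65957584 in HMU replicates 1 to 3. Genes with at least 10 counts numbered 18005 ± 38.5 in the PBS libraries and 17612 ± 73.7 in the HMU libraries (SD, n = 3, as for all levels that follow). Transcripts of the mitochondrial genome held 5.05% ± 0.263 of counts in PBS and 6.19% ± 0.101 in HMU libraries, with no overlap between the groups; 3 libraries against 3 cannot give a two-sided exact permutation p under 0.1. Ribosomal protein genes held 4.45% ± 0.0750 and 5.17% ± 0.840, and HMU replicate 2 stood highest at 6.09%.

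The first principal component, with 76.9% of the variance, parted the HMU from the PBS libraries, and the next one, with 10.8%, spread the HMU libraries. Chi-square per degree of freedom over genes was 5.62 to 6.92 between PBS libraries. Between HMU replicates 1 and 3 it was 16.3, and HMU replicate 2 differed from them by 78.9 and 135. No pair of libraries agreed within sampling noise. HMU replicate 2 thus stood apart from the other HMU libraries.

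The comparison of HMU with PBS asks how this bacterium changed transcript levels in vaginal epithelial cells. ELF3, an epithelial transcription factor, the neutrophil chemokine CXCL8 and HAS3, which makes hyaluronan, were among the genes that rose at least 16-fold; CHAC1, which degrades glutathione, and SMAD6, an inhibitor of BMP signalling, were among those that fell at least 16-fold. Of 17990 genes tested, 4503 were higher and 4547 lower after HMU by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least a 2-fold change was fitted for 1456 of the higher and 1365 of the lower genes. At 4-fold or more these numbers were 550 and 267, and at 16-fold or more 158 and 29. The 3 HMU values lay all above or all below the 3 PBS values for 11207 genes, or 62.3%, where chance gives 10%. Among protein-coding genes 3759 were higher and 3810 lower, and among long non-coding RNA genes 380 were higher and 535 lower.

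The balance of higher and lower genes depended on the scaling. TMM scaling set 49.8% of the called genes as higher. With library sizes only, the median log2 fold change of all tested genes moved to -0.28, and 2442 genes were higher and 7942 lower, which is 23.5% higher. On log2(TPM + 1) 1975 were higher and 9153 lower, and on log2(FPKM + 1) 2441 were higher and 7612 lower. The genes that rose at least 2-fold held 4.91% ± 0.0549 of counts in PBS and 13.3% ± 0.363 in HMU libraries. Changes below are relative to the TMM scale, on which the median gene did not shift. With library sizes only, the medians of all 33 lists moved down by about the same shift as the median of all genes.

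**Figure D1:**
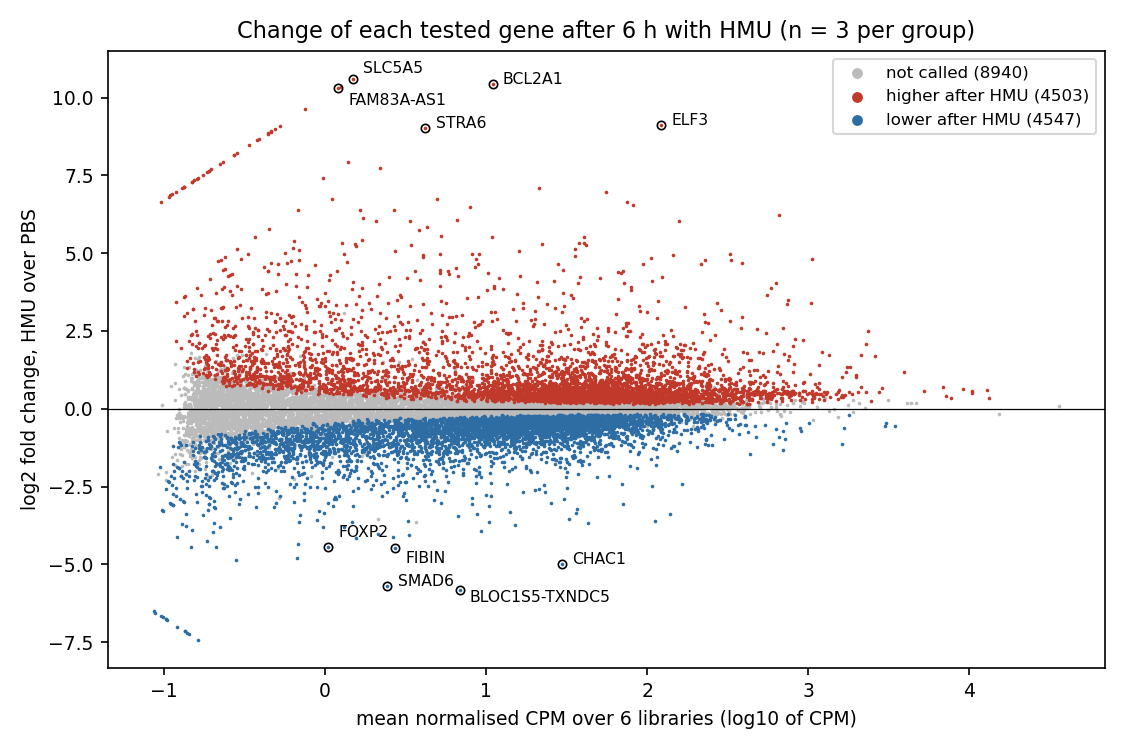
Each point is 1 of 17990 tested genes, with its mean TMM-normalised CPM over the 6 libraries on a log10 scale (x axis) and its fitted log2 fold change of HMU over PBS (y axis). Red points are the 4503 genes called higher and blue points the 4547 called lower; circles mark the 5 largest fitted rises and 5 largest fitted falls among called genes with a mean of at least 1 CPM and no overlap between the groups, LOC genes, pseudogenes and small RNAs left out, and points of genes with 0 counts in 1 group, in diagonal lines at the left, depend on the prior count.

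Genes of extreme fold are described here among called genes with a mean of at least 1 CPM and no overlap between the groups, without LOC genes, pseudogenes and small RNAs. The 5 with the largest fitted rise were SLC5A5, BCL2A1, FAM83A-AS1, ELF3 and STRA6. Where PBS counts are 0 or few the fitted value depends on the prior count, so no order is given among them. SLC5A5, the sodium-iodide symporter (gene ID 6528, chromosome 19 from 17871945 to 17895174, GRCh38), had 0 counts in the PBS libraries and 2.98 ± 0.184 CPM after HMU, at least 71.0-fold above the floor of 3 counts per library. BCL2A1, an anti-apoptotic BCL2 relative (gene ID 597, chromosome 15 from 79960892 to 79971196), had 3 PBS counts, all in PBS replicate 3, and 21.9 ± 2.09 CPM after HMU, a ratio of 1562 with a 95% counting interval from 534 to 7576. STRA6, the receptor for retinol-binding protein (gene ID 64220, chromosome 15 from 74179466 to 74212259), had 3 PBS counts, all in PBS replicate 2, and 8.37 ± 1.29 CPM after HMU, a ratio of 596 with a counting interval from 204 to 2896. Without the library that holds those counts, either gene has 0 PBS counts. ELF3 (gene ID 1999, chromosome 1 from 202010587 to 202017183) went from 0.434 ± 0.0681 to 243 ± 18.5 CPM (log2 fold change 9.12 ± 0.13 SE, edgeR adjusted p = 9.2e-08). The antisense transcript FAM83A-AS1 (gene ID 100131726, chromosome 8 from 123201172 to 123202743) had 0 PBS counts and 2.41 ± 0.30 CPM after HMU, at least 57.3-fold above the floor. Its partner FAM83A, chosen after its values were seen, was at 70.7 to 74.1 CPM in PBS and at 1154 to 1251 CPM after HMU (log2 fold change 4.05 ± 0.071 SE). Whether the counting used strand is not given in the sources used here, so reads of the pair may be shared.

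The 5 with the largest fitted fall under the same limits were BLOC1S5-TXNDC5, SMAD6, CHAC1, FIBIN and FOXP2. SMAD6 (gene ID 4091, chromosome 15 from 66702236 to 66782849) went from 4.77 ± 0.826 to 0.0907 ± 0.0285 CPM (log2 fold change -5.70 ± 0.28 SE, edgeR adjusted p = 4.2e-06), and CHAC1 (gene ID 79094, chromosome 15 from 40953471 to 40956512) from 57.1 ± 7.53 to 1.82 ± 0.108 CPM (log2 fold change -4.97 ± 0.13 SE, edgeR adjusted p = 2.6e-07). FIBIN, a secreted protein gene (gene ID 387758, chromosome 11 from 26994112 to 26997087), fell from 5.19 ± 0.134 to 0.231 ± 0.0485 CPM, and FOXP2, a forkhead transcription factor (gene ID 93986, chromosome 7 from 114086327 to 114693765), from 2.01 ± 0.267 to 0.0892 ± 0.0570 CPM. The readthrough gene BLOC1S5-TXNDC5 (gene ID 100526836, chromosome 6 from 7881250 to 8064414) had a fitted log2 fold change of -5.82 ± 2.05 SE and an edgeR adjusted p of 0.047, but this rested on PBS replicate 3, where it reached 39.25 CPM against 0.551 and 0.489 in the other PBS libraries. Without that library its log2 fold change was -1.13 and it was not called (edgeR adjusted p = 0.078). Nor was it called without HMU replicate 1, 2 or 3 (edgeR adjusted p = 0.12, 0.066 and 0.099), with limma-voom (0.32), with no filter on low counts (0.10) or on log2(TPM + 1) and log2(FPKM + 1) (0.20 and 0.25). Without HMU replicate 1, 2 or 3 the log2 fold change stayed at -6.29, -5.47 and -5.80. It was smaller with limma-voom (-3.35) and on log2(TPM + 1) and log2(FPKM + 1) (-1.74 and -1.23).

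Inflammatory cytokines and chemokines rose as a group. Of 36 tested members, 31 rose and 3 fell (31 and 4 adjusted over the list alone). Their median log2 fold change was 3.15, with a camera adjusted p = 2.1e-13, and adjusted p = 0.16 with an estimated correlation. CXCL8 went from 0.887 ± 0.224 to 110 ± 22.4 CPM (log2 fold change 6.95 ± 0.23 SE, edgeR adjusted p = 6.9e-07). CSF3, the granulocyte colony-stimulating factor, reached 4.36 ± 0.404 CPM from 0.0188 ± 0.0326, with all 4 PBS counts in PBS replicate 1. Its fitted log2 fold change was 7.73, and 11.13 without that library. Of 34 feedback and target genes of NF-kB, the transcription factor behind many inflammatory genes, 30 rose and 1 fell (30 and 1 adjusted over the list alone). The list median was 1.54, with a camera adjusted p = 2.1e-13, and adjusted p = 0.16 with an estimated correlation. TNFAIP2 in this list went from 20.3 ± 1.23 to 636 ± 70.1 CPM (log2 fold change 4.97 ± 0.11 SE), and BCL2A1, above, is also a member; 0 members were lower without PBS replicate 3.

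Antimicrobial peptide and protein genes were measured for 20 of 38 listed members, of which 19 rose and 0 fell (19 and 0 adjusted over the list alone). The median change was 2.78, with a camera adjusted p = 6.8e-12, and adjusted p = 0.16 with an estimated correlation. WFDC12, a whey acidic protein family inhibitor, went from 0.140 ± 0.0273 to 7.54 ± 0.694 CPM, and S100A7A, a psoriasin relative, from 0.172 ± 0.107 to 6.69 ± 1.67 CPM; S100A7A has a near-identical neighbour, so its share of reads is uncertain. Its log2 fold change of 5.26 was 5.87 without PBS replicate 3. Interferon-stimulated genes were all measured, and of 45 members, 35 rose and 0 fell (37 and 0 adjusted over the list alone). The median log2 change came to 0.71 (0.43 with library sizes only), with a camera adjusted p = 2.2e-08, and adjusted p = 0.29 with an estimated correlation. The guanylate-binding GTPase gene GBP1 went from 4.18 ± 0.457 to 55.5 ± 3.14 CPM (log2 fold change 3.73 ± 0.10 SE) and the exonuclease gene ISG20 from 2.78 ± 0.253 to 20.7 ± 4.06 CPM. Scaled by library sizes only, 21 interferon-stimulated genes were higher and 3 lower. Pattern recognition receptors and adaptors were mixed: of 33, 15 rose and 8 fell (15 and 8 adjusted over the list alone), and the list did not pass. Its median was 0.30 (0.021 with library sizes only and 0.13 without PBS replicate 1), with a camera adjusted p = 0.080, and adjusted p = 0.41 with an estimated correlation. It passed without HMU replicate 2 (camera adjusted p = 0.045) and with library sizes only (0.030). In this list NLRP3, an inflammasome sensor, went from 0.657 ± 0.0261 to 12.6 ± 1.202 CPM, and TLR2, the receptor for bacterial lipoproteins, from 5.40 ± 0.462 to 26.1 ± 3.78 CPM (log2 fold change 2.27 ± 0.13 SE, edgeR adjusted p = 8.3e-06).

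Genes of matrix breakdown, protease inhibition and wound response also rose, 24 of 34 members with 1 lower (24 and 1 adjusted over the list alone). The median of the list was 1.78, with a camera adjusted p = 3.1e-10, and adjusted p = 0.16 with an estimated correlation. HAS3 went from 17.2 ± 0.869 to 1289 ± 195 CPM (log2 fold change 6.22 ± 0.14 SE, edgeR adjusted p = 1.7e-07) and the tissue plasminogen activator gene PLAT from 2.11 ± 0.316 to 81.7 ± 4.29 CPM. Library sizes alone gave 23 members higher and 6 lower, and 3 were lower without HMU replicate 3. Of 45 genes of squamous differentiation and the cornified envelope, 32 rose and 7 fell (32 and 7 adjusted over the list alone). Their median log2 fold change was 0.96, with a camera adjusted p = 1.2e-07, and adjusted p = 0.26 with an estimated correlation. IVL, which encodes involucrin, a precursor of the cornified envelope, went from 7.18 ± 1.08 to 205 ± 20.4 CPM (log2 fold change 4.83 ± 0.14 SE, edgeR adjusted p = 3.8e-07), and SPRR2F, of a family with similar copies between which reads can be split, from 0.191 ± 0.0279 to 13.01 ± 1.83 CPM. The lower genes of this list numbered 11 with library sizes only.

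Of 38 genes of tight junctions, adherens junctions and desmosomes, 22 rose and 11 fell (22 and 11 adjusted over the list alone). The list median was 0.43 (0.15 with library sizes only), with a camera adjusted p = 0.016, and adjusted p = 0.45 with an estimated correlation. The claudin gene CLDN4 went from 22.9 ± 0.120 to 130 ± 11.2 CPM (log2 fold change 2.50 ± 0.083 SE) and the paracingulin gene CGNL1 from 1.21 ± 0.285 to 6.55 ± 1.249 CPM. Library sizes alone gave 17 members higher and 14 lower. Without PBS replicate 1, and also without PBS replicate 3, 6 were lower. Basal keratinocyte and hemidesmosome genes numbered 25, of which 14 rose and 3 fell (14 and 3 adjusted over the list alone). The median change was 0.34 (0.062 with library sizes only), with a camera adjusted p = 0.0083, and adjusted p = 0.24 with an estimated correlation; with library sizes only, 8 were higher and 6 lower, and with a length and GC correction 6 were lower. LAMB3, a chain of laminin-332, went from 532 ± 13.6 to 1892 ± 141 CPM, while SOX2, a progenitor transcription factor, fell from 6.02 ± 0.553 to 0.491 ± 0.0780 CPM (log2 fold change -3.61 ± 0.16 SE). Of 14 mucin and glycocalyx genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone). The median log2 change came to 1.74, with a camera adjusted p = 0.0083, and adjusted p = 0.24 with an estimated correlation. GCNT3, a mucin-type glycosyltransferase, rose from 0.513 ± 0.0209 to 11.01 ± 0.456 CPM, and MUC15 fell from 4.53 ± 0.880 to 0.772 ± 0.345 CPM.

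**Figure D2:**
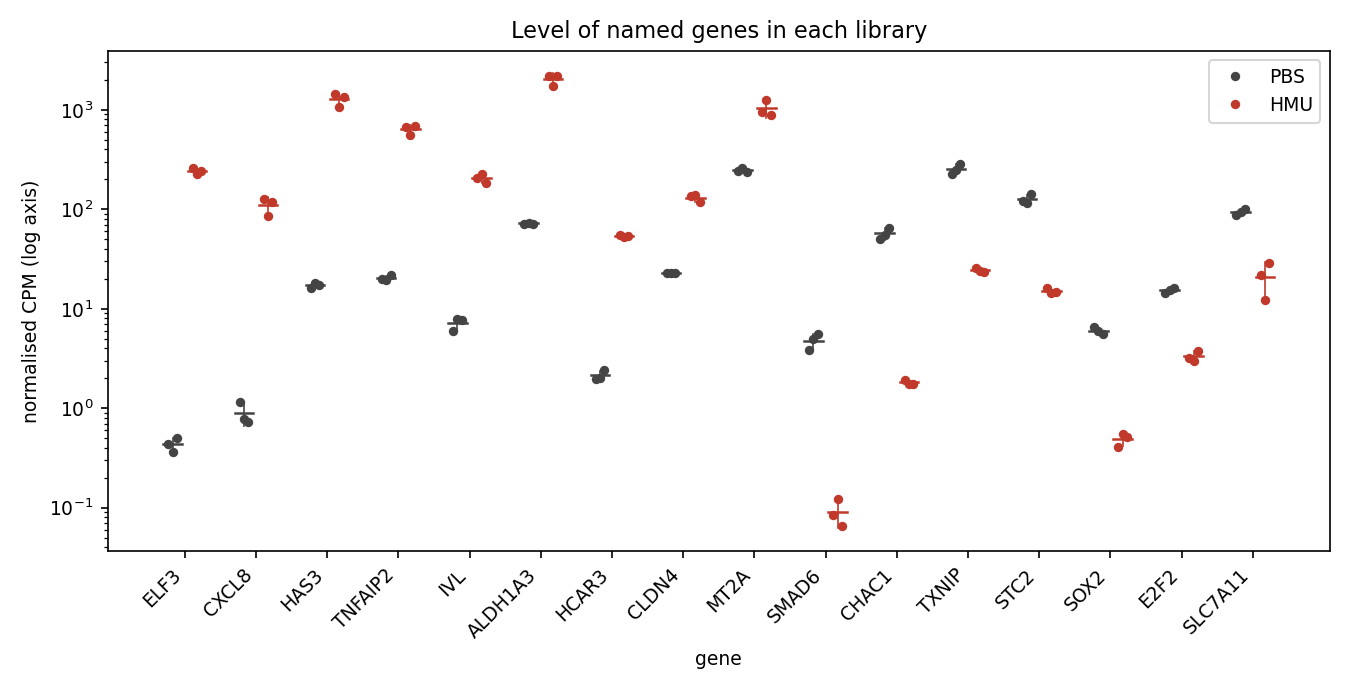
Points are the TMM-normalised CPM of 16 named genes in each library on a log axis, PBS in grey and HMU in red, with horizontal bars for the mean of 3 libraries and vertical bars for 1 SD. For each of these genes the 3 HMU libraries lie on one side of the 3 PBS libraries, as for ELF3 at 0.434 CPM in PBS and 243 CPM after HMU, and CHAC1 at 57.1 and 1.82 CPM.

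Of 26 genes in the list of EGF receptor ligands and MAPK feedback, 13 rose and 6 fell (13 and 6 adjusted over the list alone), and 11 were higher and 8 lower with library sizes only. The list test lay next to the threshold, with a camera adjusted p = 0.0497, and adjusted p = 0.51 with an estimated correlation, and the median was 0.45 (0.17 with library sizes only and 0.29 with a length and GC correction). That call ended with RLE scaling (camera adjusted p = 0.052), with a length and GC correction (0.057), and without PBS replicate 1, HMU replicate 1 or HMU replicate 3 (0.061, 0.062 and 0.11). Its lower members numbered 3 without PBS replicate 3. LIF, an interleukin-6 family cytokine, went from 1.34 ± 0.150 to 19.0 ± 2.81 CPM and the EGF receptor ligand EREG from 48.1 ± 4.15 to 401 ± 157 CPM (log2 fold change 3.06 ± 0.29 SE). LIF is also a member of the cytokine list and IER3 of the NF-kB list, so this list is not independent of those. Immediate early AP-1 and EGR genes were mixed, and of 27 tested members, 12 rose and 6 fell (12 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.096, and adjusted p = 0.45 with an estimated correlation). Its median was 0.13 (-0.15 with library sizes only and -0.029 with a length and GC correction), which turns the direction. FOSL1, an AP-1 subunit, went from 24.4 ± 4.15 to 125 ± 9.82 CPM and MAFF, a small MAF factor, from 18.1 ± 0.680 to 49.7 ± 3.60 CPM.

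Lactate, pH and acid handling genes were tested because lactobacilli make lactic acid. Of 26, 13 rose and 4 fell (13 and 5 adjusted over the list alone). The median of the list was 0.33 (0.052 with library sizes only and 0.21 with a length and GC correction), with a camera adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation; 1, 0 and 1 members were lower without PBS replicate 1, PBS replicate 3 and HMU replicate 1, and 8 with library sizes only. The hydroxycarboxylic acid receptor gene HCAR3, nearly identical to its neighbour HCAR2, went from 2.14 ± 0.25 to 54.0 ± 1.47 CPM and the receptor gene GPR132 from 0.0979 ± 0.0370 to 2.64 ± 0.604 CPM. Of 15 genes in the aryl hydrocarbon receptor list, 8 rose and 2 fell (9 and 2 adjusted over the list alone). The 2 lower ones, named after their values were seen, were not targets but the receptor gene AHR and its partner ARNT. The list's median log2 fold change was 0.52 (0.23 with library sizes only), with a camera adjusted p = 0.0059, and adjusted p = 0.29 with an estimated correlation. ALDH1A3, which makes retinoic acid, went from 72.1 ± 0.402 to 2037 ± 279 CPM (log2 fold change 4.82 ± 0.12 SE, edgeR adjusted p = 2.3e-07). The gene IL24, also a member of the cytokine list, went from 0.219 ± 0.0549 to 10.3 ± 1.63 CPM. With library sizes only, 4 members of the aryl hydrocarbon receptor list were lower. Of 17 metallothionein and metal handling genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone). The list median was 0.58 (0.29 with library sizes only and 0.36 with a length and GC correction), with a camera adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation. MT1A went from 0.467 ± 0.0783 to 2.29 ± 0.282 CPM and MT2A from 246 ± 14.1 to 1033 ± 201 CPM, and reads of this gene family can be split between its copies. With a length and GC correction the log2 fold change of MT1A was 1.69 instead of 2.29.

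Genes of the ATF4 integrated stress response list moved down. Of 35, 7 rose and 24 fell (7 and 24 adjusted over the list alone). The median change was -0.53 (-0.81 with library sizes only), with a camera adjusted p = 2.9e-04, and adjusted p = 0.37 with an estimated correlation. Besides CHAC1, the secreted glycoprotein gene STC2 fell from 126 ± 13.4 to 15.1 ± 0.972 CPM (log2 fold change -3.06 ± 0.10 SE, edgeR adjusted p = 6.7e-07). NRF2 oxidative stress genes were mixed: of 34, 15 rose and 8 fell (15 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.11, and adjusted p = 0.47 with an estimated correlation). Its median was 0.11 (-0.18 with library sizes only and 0.015 with a length and GC correction), and 5 members were lower without PBS replicate 3. Library sizes alone gave 9 higher and 15 lower, and a length and GC correction gave 13 and 13. TXNRD1, thioredoxin reductase, rose from 38.3 ± 1.75 to 142 ± 29.6 CPM, while SLC7A11, the cystine transporter gene and also an ATF4 list member, fell from 94.1 ± 6.86 to 20.96 ± 8.33 CPM (log2 fold change -2.16 ± 0.27 SE). Cytosolic heat shock genes leaned upward, and of 24 tested members, 14 rose and 1 fell (15 and 1 adjusted over the list alone). The median log2 change came to 0.46 (0.18 with library sizes only), with a camera adjusted p = 0.0024, and adjusted p = 0.37 with an estimated correlation; with library sizes only 10 were higher and 6 lower, and 2 were lower without HMU replicate 2 or HMU replicate 3. DNAJB1 went from 233 ± 11.3 to 805 ± 18.1 CPM and DNAJA1, another HSP70 cochaperone gene, from 58.5 ± 2.55 to 106 ± 13.04 CPM. Endoplasmic reticulum chaperones and genes of the unfolded protein response also leaned upward, and of 24 tested members, 12 rose and 1 fell (12 and 1 adjusted over the list alone). The median of the list was 0.27 (-0.012 with library sizes only and 0.17 with a length and GC correction), with a camera adjusted p = 0.022, and adjusted p = 0.37 with an estimated correlation. HSPA5, the main chaperone of that compartment, went from 527 ± 24.7 to 928 ± 58.9 CPM, and DNAJB9 from 7.90 ± 0.385 to 14.5 ± 3.80 CPM. DNAJB9 was not called on log2(TPM + 1) or log2(FPKM + 1) (limma-trend adjusted p = 0.13 and 0.051). With library sizes only 6 of these genes were higher and 6 lower, and the call ended (camera adjusted p = 0.083). Without PBS replicate 1, 2 or 3 or HMU replicate 1, 0 were lower.

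Genes of oxygen response, glycolysis and sterol synthesis included both rises and falls. Hypoxia response genes did not pass: of 38, 9 rose and 17 fell (9 and 17 adjusted over the list alone). Their median log2 fold change was -0.25 (-0.53 with library sizes only), with a camera adjusted p = 0.092, and adjusted p = 0.52 with an estimated correlation. The counts were 6 higher and 23 lower with library sizes only. ANGPTL4, a lipase inhibitor, rose from 2.83 ± 0.383 to 26.3 ± 3.79 CPM, while TXNIP, which binds thioredoxin and limits glucose uptake, fell from 254 ± 30.1 to 24.5 ± 1.24 CPM (log2 fold change -3.37 ± 0.10 SE, edgeR adjusted p = 5.4e-07). Of 22 genes in the glycolysis list, 10 rose and 3 fell (11 and 3 adjusted over the list alone). The list median was 0.22 (-0.068 with library sizes only, 0.06 with a length and GC correction and 0.13 without HMU replicate 2), with a camera adjusted p = 0.043, and adjusted p = 0.45 with an estimated correlation. SLC16A3, a lactate exporter gene, rose from 121 ± 2.58 to 239 ± 42.7 CPM, and ENO2, an enolase gene, fell from 9.79 ± 0.174 to 4.95 ± 0.412 CPM. The glycolysis call ended with library sizes only, where 5 were higher and 6 lower (camera adjusted p = 0.24), with a length and GC correction (0.21), and without PBS replicate 1, 2 or 3 (0.061, 0.054 and 0.067); 6 members were higher without PBS replicate 3. The cholesterol and fatty acid synthesis list, which also holds sterol transporter genes, fell on balance: of 37, 5 rose and 20 fell (5 and 20 adjusted over the list alone). The median change was -0.21 (-0.49 with library sizes only), with a camera adjusted p = 0.0497, and adjusted p = 0.40 with an estimated correlation. ABCA1, a cholesterol exporter gene, rose from 33.3 ± 0.460 to 76.9 ± 30.3 CPM and ABCG1, another sterol transporter gene, fell from 22.3 ± 0.823 to 9.65 ± 1.27 CPM. ABCA1 was not called on log2(TPM + 1) or log2(FPKM + 1) (limma-trend adjusted p = 0.10 and 0.058). The list's call ended with RLE scaling (camera adjusted p = 0.053), with a filter of at least 1 CPM (0.059), and without PBS replicate 1, PBS replicate 3 or HMU replicate 1 (0.070, 0.055 and 0.083), where 11, 12 and 12 members were lower and 3 were higher each time. Without PBS replicate 2, 3 were higher, and library sizes alone gave 3 higher and 25 lower.

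Genes of DNA replication and S phase fell, 23 of 40 with none higher (0 and 23 adjusted over the list alone). The median log2 change came to -0.27 (-0.55 with library sizes only), with a camera adjusted p = 9.4e-06, and adjusted p = 0.31 with an estimated correlation. Scaled by library sizes only, 37 were lower, and 34 were lower without HMU replicate 2. The transcription factor gene E2F2 fell from 15.3 ± 0.821 to 3.33 ± 0.405 CPM (log2 fold change -2.20 ± 0.11 SE, edgeR adjusted p = 4.6e-06), and the cyclin gene CCNE2 from 6.21 ± 0.476 to 1.53 ± 0.622 CPM. Of 40 mitotic genes, 2 rose and 19 fell (2 and 19 adjusted over the list alone). The median of the list was -0.20 (-0.48 with library sizes only), with a camera adjusted p = 0.0083, and adjusted p = 0.31 with an estimated correlation; with library sizes only 34 were lower and 0 higher, and 5 were higher without HMU replicate 2. The motor protein gene CENPE went from 80.3 ± 2.98 to 45.04 ± 7.002 CPM and HMMR, a hyaluronan-binding spindle protein gene, from 43.9 ± 1.101 to 24.1 ± 3.14 CPM. The p53 target list did not pass, and of 28 tested members, 7 rose and 13 fell (8 and 13 adjusted over the list alone). Their median log2 fold change was -0.13 (-0.41 with library sizes only, -0.25 with a length and GC correction and -0.21 without HMU replicate 2), with a camera adjusted p = 0.22, and adjusted p = 0.40 with an estimated correlation; 4 were higher without PBS replicate 3, and 4 with library sizes only. PLK3, a stress-responsive kinase gene, rose from 11.5 ± 1.01 to 30.3 ± 2.38 CPM, and SESN2, a sestrin gene also controlled by ATF4, fell from 51.4 ± 4.96 to 18.3 ± 0.776 CPM. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, gave 2 higher and 6 lower of 16 (2 and 6 adjusted over the list alone). The list median was -0.44 (-0.72 with library sizes only), with a camera adjusted p = 0.085, and adjusted p = 0.40 with an estimated correlation. Their most abundant member, H1-2, went from 3.35 ± 0.0749 to 5.42 ± 1.28 CPM, and was not called with library sizes only or on log2(TPM + 1) or log2(FPKM + 1). Without PBS replicate 2 the histone list passed (camera adjusted p = 0.025), and 3 members were lower without PBS replicate 3. The higher members numbered 1 without PBS replicate 1, PBS replicate 2 or HMU replicate 2, and library sizes alone gave 0 higher and 8 lower.

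Lists of ribosomal and mitochondrial genes were also fixed as background. Of 76 cytosolic ribosomal protein genes, 74 rose and 0 fell (76 and 0 adjusted over the list alone). The median change was 0.50 (0.22 with library sizes only), with a camera adjusted p = 5.6e-10, and adjusted p = 0.45 with an estimated correlation. RPL4 went from 1569 ± 18.1 to 2167 ± 248 CPM and was not called with library sizes only or on log2(TPM + 1) or log2(FPKM + 1). By library the median log2 difference from the PBS mean was 0.44, 0.78 and 0.25 in HMU replicates 1 to 3. Library sizes alone gave 3 members higher, and 49, 48 and 43 were higher without PBS replicate 1, 2 and 3. Reads of these genes can be split with their many pseudogenes. Of 13 mitochondrially encoded transcripts, 12 rose and 0 fell (12 and 0 adjusted over the list alone). The median log2 change came to 0.53 (0.24 with library sizes only and 0.17 with a length and GC correction), with a camera adjusted p = 1.4e-04, and adjusted p = 0.31 with an estimated correlation, and COX1 went from 10116 ± 526 to 15389 ± 801 CPM, though it was not called on log2(TPM + 1) or log2(FPKM + 1). The list's call ended with a length and GC correction, where 6 members were higher (camera adjusted p = 0.057). Of 49 nuclear-encoded oxidative phosphorylation genes, 23 rose and 1 fell (21 and 1 adjusted over the list alone). The median of the list was 0.33 (0.049 with library sizes only, 0.087 with a length and GC correction and 0.18 without HMU replicate 2), with a camera adjusted p = 0.0021, and adjusted p = 0.54 with an estimated correlation. ATP5F1B, its most abundant member, had 631 ± 11.6 CPM in PBS and 709 ± 60.5 CPM in HMU libraries and was not called (edgeR adjusted p = 0.099), except without HMU replicate 3, and was lower on log2(TPM + 1). With library sizes only 2 were higher and 8 lower (camera adjusted p = 0.064), with a length and GC correction 12 were higher and 6 lower (0.22), and 11, 9, 7 and 13 were higher without PBS replicates 1, 2 and 3 and HMU replicate 1.

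Marker lists of other cell types were fixed as background. Of 9 simple glandular epithelium markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone). Their median log2 fold change was 0.78 (0.50 with library sizes only and 0.47 with a length and GC correction), with a camera adjusted p = 0.033, and adjusted p = 0.42 with an estimated correlation, and KRT19 went from 433 ± 6.33 to 770 ± 159 CPM; the call ended without HMU replicate 2 (camera adjusted p = 0.0503) and with a length and GC correction (0.056), and library sizes alone gave 2 markers lower. The leukocyte list did not pass, and of 9 tested markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone). The list median was 0.66 (0.38 with library sizes only), with a camera adjusted p = 0.22, and adjusted p = 0.40 with an estimated correlation; CD68, a lysosomal protein gene and its most abundant member, went from 57.8 ± 1.12 to 121 ± 7.39 CPM. Fibroblast markers did not pass either: of 10, 2 rose and 3 fell (2 and 3 adjusted over the list alone). Their median was -0.04 (-0.32 with library sizes only, -0.011 without PBS replicate 1, -0.073 without PBS replicate 2, -0.09 without HMU replicate 1 and -0.015 without HMU replicate 2). Their mean was 0.75, which includes 1 marker with 0 PBS counts, whose fitted value depends on the prior count. The test leaned down (camera adjusted p = 0.96, and adjusted p = 0.97 with an estimated correlation). SPARC had 483 ± 14.3 CPM in PBS and 510 ± 9.05 CPM in HMU libraries (edgeR adjusted p = 0.30); with library sizes only, and on log2(TPM + 1) and log2(FPKM + 1), SPARC was lower. Library sizes alone gave 6 fibroblast markers lower, and a length and GC correction 5. Of 6 endothelial markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone). The median change was 0.56 (0.27 with library sizes only), with a camera adjusted p = 0.24, and adjusted p = 0.41 with an estimated correlation, and EGFL7 had 4.97 ± 0.260 CPM in PBS and 5.92 ± 1.74 CPM in HMU libraries (edgeR adjusted p = 0.33), though it was called without HMU replicate 3.

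In all, 24 of the 33 lists passed camera with the preset correlation and none passed with an estimated correlation. By fry, which tests each list on its own, 32 passed in one direction and 33 in either. Fry does not ask whether members changed more than other genes. Of all 17990 tested genes, 4503 were higher and 4547 lower, so a list of average genes can pass it. Fibroblast markers, with a median of -0.04, passed as well. Medians were the same with genes at 0 counts in 1 group placed at their bound.

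**Figure D3:**
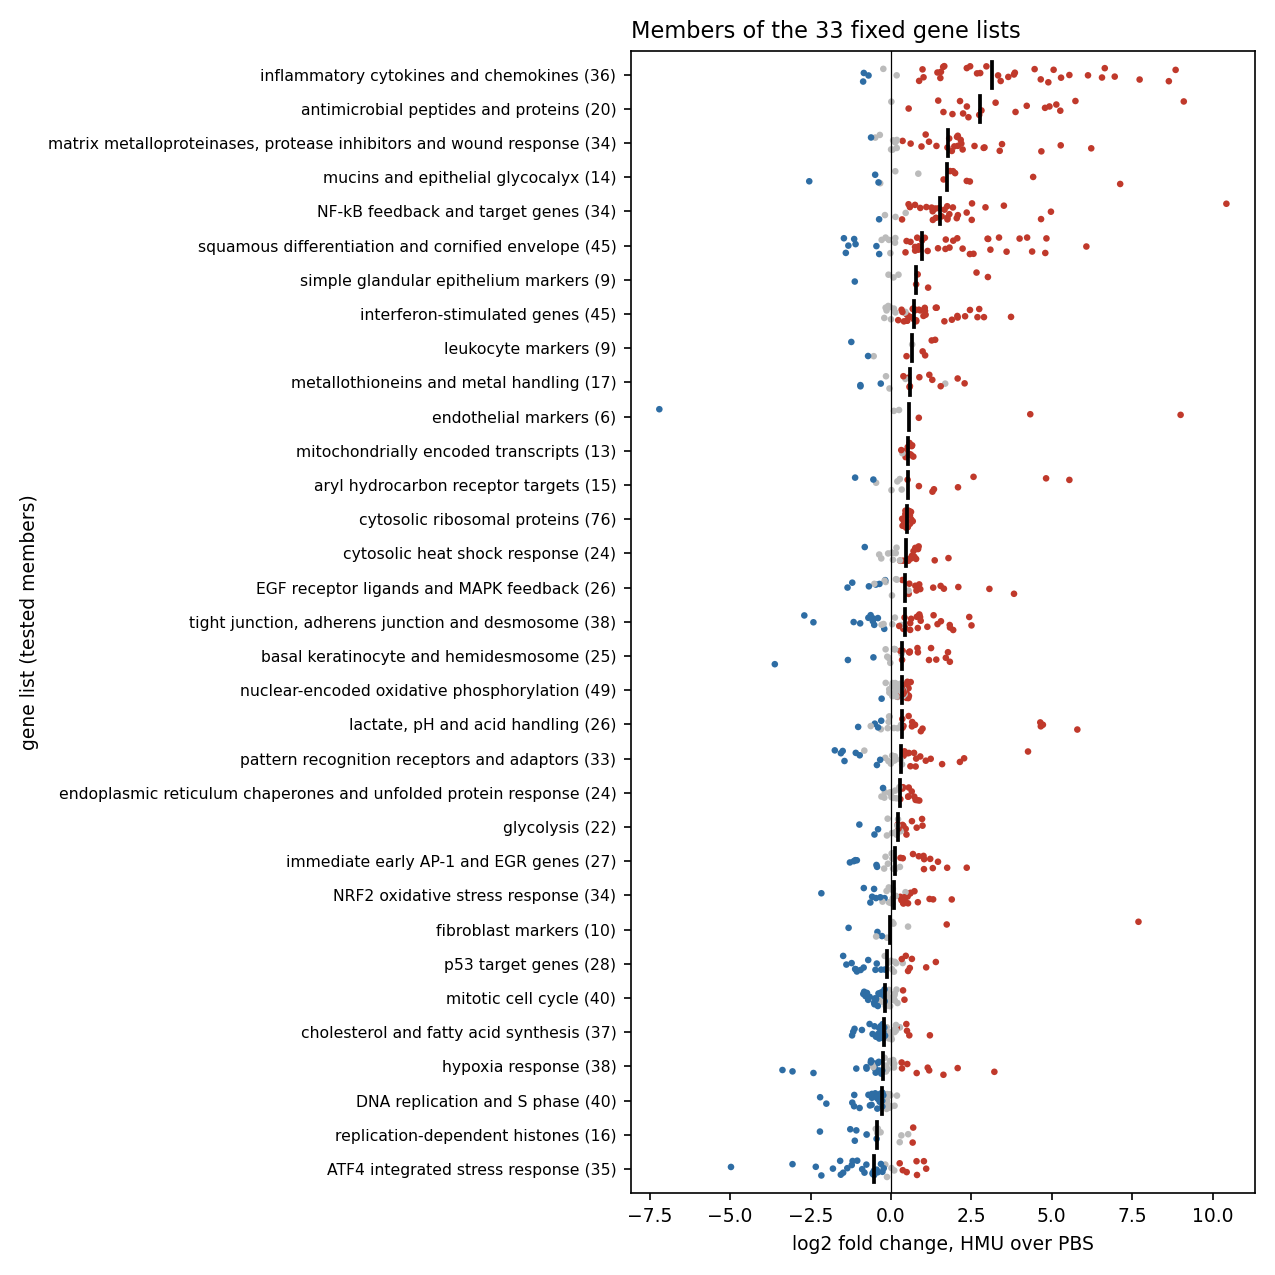
Points are the fitted log2 fold changes of HMU over PBS (x axis) of the tested members of each of 33 gene lists (y axis, with the number of tested members), red where called higher, blue where called lower and grey where not called; black bars are list medians. Cytokines and chemokines have the highest median, 3.15, and ATF4 genes the lowest, -0.53; with library sizes only, medians near 0 such as those of glycolysis, NRF2, immediate early and endoplasmic reticulum genes turn negative, and points of genes with 0 counts in 1 group depend on the prior count.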

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

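The robust fit, the length and GC correction, the filter on overlapping genes and the scaling of list tests were chosen after seeing the data. Leaving out 1 library gave 3395 to 5459 genes higher and 3382 to 5487 lower, most without HMU replicate 2, and 21 to 24 lists. DESeq2 gave 4460 and 4477, RLE scaling 4608 and 4445, the robust fit 4452 and 4515, and the length and GC correction 4614 and 5694. Like totals do not mean the same genes. Of the 4503 higher and 4547 lower genes, DESeq2 kept 4213 and 4215, with 0 called the opposite way. The length and GC correction kept 3791 and 4173, with 12 opposite, and log2(TPM + 1) gave 92 opposite. Across genes the fold change itself correlated with length at -0.22 and with GC content at 0.27 (Spearman). Counts moved by over 1.5 times with library sizes only (2442 higher, 7942 lower), on log2(TPM + 1) (1975 and 9153), log2(TPM + 0.1) (1965 and 9126) and log2(FPKM + 1) (2441 and 7612); the median of all genes moved with them, to -0.28 with library sizes only. Stricter thresholds call fewer by construction: 1456 and 1365 at a log2 fold change of at least 1, 2967 lower at an adjusted p under 0.01, and 1559 and 1371 with glmTreat against 1.5-fold. An estimated correlation ended all 24 list calls, leaving 0, with a smallest camera adjusted p of 0.16. The mucin, lactate and metallothionein lists had estimated correlations of -0.045, -0.029 and -0.051, below the preset 0.01. Their calls ended too, so correlation among members does not by itself account for the losses. With an estimated correlation, camera also rests on the few residual degrees of freedom of 6 libraries. Fry called 32. By fry the direction of fibroblast markers (adjusted p = 0.0468) and endothelial markers (0.00262) was the opposite; the cause was not tested. ATP5F1B turned to -0.23 on log2(TPM + 1), and SPARC to -0.20 with library sizes only, -0.32 on log2(TPM + 1) and -0.20 on log2(FPKM + 1). Of 66 named genes, 9 changed call or sign under some alternative. The replicate block, for numbers that the labels do not say are paired, gave 4296 higher, 4350 lower and 21 lists, not those of EGF receptor ligands (camera adjusted p = 0.066), glycolysis (0.052) and cholesterol (0.066); same-number correlations were -0.019, 0.035 and 0.048, and not every sample correlated best with its own number. Depth limits genes near the floor of 3 counts, 0.0455 to 0.0467 CPM.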

Other observations

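The 3 added gene lists were chosen after the values had been seen, as were the depth test of HMU replicate 2, the test without that library for ribosomal protein genes and the use of the spread between HMU libraries in judging length and GC bias. Genes of complement and the acute phase, which take part in early defence, were higher after HMU. SAA2 went from 1.71 ± 0.274 to 78.7 ± 2.29 CPM and CFB, complement factor B, from 6.25 ± 0.226 to 130 ± 4.32 CPM (log2 fold change 4.38 ± 0.076 SE, edgeR adjusted p = 9.2e-08). SAA1, a similar gene of the SAA2 family, went from 8.11 ± 0.956 to 135 ± 28.3 CPM. Reads can be split between these copies, so the share of each is uncertain. Leaving out the 4 genes that prompted the list, 10 of 15 measured members rose and 1 fell, with a median log2 fold change of 0.70 (camera adjusted p = 0.00037 over the 3 lists added, and adjusted p = 0.045 with an estimated correlation). In each added list the other members were also listed after the values had been seen. Their p-values are therefore descriptive and cannot be set against those of the 33 fixed lists. Library size scaling gave 9 higher and 2 lower, with a median of 0.42. Of the 15, C3 went from 4.58 ± 0.209 to 33.4 ± 4.05 CPM. The complement regulators CD55 and CD59 rose as well, CD55 by a log2 fold change of 1.40 ± 0.11 SE and CD59 by 1.78 ± 0.065 SE.

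Genes of BMP signalling and its SMAD targets were mostly lower. Without the 5 genes that prompted the list, 2 of 20 members rose and 14 fell, with a median of -0.79 (camera adjusted p = 0.00087, and adjusted p = 0.096 with an estimated correlation). ID3, a target of BMP signalling, fell from 180 ± 8.14 to 32.6 ± 3.89 CPM (log2 fold change -2.47 ± 0.099 SE, edgeR adjusted p = 1.5e-06), while ID1, of the same family, rose from 127 ± 2.21 to 476 ± 62.8 CPM. A list of retinoid and vitamin D metabolism genes was prompted by STRA6, ALDH1A3, CYP26B1, TGM2 and CYP24A1. It held no shared direction beyond those 5. Of 15 others 5 rose and 5 fell, with a median of -0.12 (-0.40 with library sizes only). Their log2 fold changes ran from -1.01 for ALDH1A1 to 3.92 for DHRS3, so the rises reached further than the falls. The test leaned upward (camera adjusted p = 0.71, and adjusted p = 0.71 with an estimated correlation).

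HMU replicate 2 stood apart from the other HMU libraries. A loess fit on transcript length and GC content explained 46.4% of the variance over genes of its difference from HMU replicates 1 and 3, against at most 0.980% for any PBS library against the others of its group. The shares were 40.4% for HMU replicate 3 and 12.5% for HMU replicate 1, but differences within a group of 3 depend on one another. In HMU replicate 2, genes with shorter transcripts and higher GC content were relatively higher, with Spearman correlations across genes of -0.605 for length and 0.546 for GC content. Its depth argues against depth as the source, at 0.981 times the mean of the other HMU libraries. The difference correlated with the change in HMU replicates 1 and 3 at r = 0.107, with a slope of 0.033. This covers 7662 called genes with a mean of at least 1 CPM. Both quantities share the mean of HMU replicates 1 and 3, which can bias r. A slightly stronger response in this culture stays open, but one of this slope accounts for little of the difference. A candidate explanation is a difference in RNA fragmentation or library preparation, with which length and GC trends would go.

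The median log2 fold change of ribosomal protein genes was 0.50, and 0.22 with library sizes only, where 3 of 76 were called higher. HMU replicate 2 alone is argued against by a median of 0.35 without it, where all 76 genes were called higher. Reads moving from pseudogenes to their parent genes are argued against by 230 ribosomal protein pseudogenes, whose median was 0.53, with 74 called higher and 6 lower. Length and GC bias cannot be told apart from a change in the cells. After the trend over all other genes was removed the median was 0.38, which met the bound of 0.25 set beforehand. Corrected library by library, the medians in HMU replicates 1 to 3 were 0.31, 0.55 and 0.17 (SD 0.19, and 0.27 before correction). The excess over the bound was smaller than this SD, a yardstick added after the values were seen. It is the spread of single libraries, not the error of the 0.38. The median of HMU replicate 3 lay below the bound. With the per-library correction 58 genes were still higher and 0 lower, and the list passed (camera adjusted p = 7.0e-08), while the mitochondrial and oxidative phosphorylation calls ended. Of 10000 random lists matched on mean expression, 203 had a median at or above that of the ribosomal protein genes. Their members were drawn singly, while the ribosomal protein genes moved together (estimated correlation 0.98). This share therefore does not measure chance for such a list. A rise in ribosomal protein transcripts after HMU therefore stays a hypothesis, relative to the TMM scale.

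The value of BLOC1S5-TXNDC5 in PBS replicate 3 may come from reads that the counting gave to one of 2 overlapping genes. Its CPM and that of TXNDC5 summed in this library to 1.01 times the mean sum of the other PBS libraries, while TXNDC5 alone was at 87.8 CPM there against 128 and 123. A biological explanation was not tested, since the design names none for a single library. Of 118 readthrough genes tested, 27 were called, and of 417 antisense genes 169 were, and their values have the same limit.

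With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4503 genes higher and 4547 lower, and the highest count of any other split was 0 by edgeR. Of the 10 splits, 1 has as many calls, the real one. Every other split mixes PBS and HMU libraries on each side, so the difference between the groups widens its spread. Few calls were bound to follow, adjusted or not, so these counts say nothing about chance. At an unadjusted p under 0.05 the other splits gave at most 154 genes in one direction, against 5104 higher and 5175 lower in the real split; no other tool was run on them.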
